A study of Arapaima gigas with 24 samples.

How the data were processed

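Gonad and brain of 6 farmed Arapaima gigas (pirarucu, a large air-breathing freshwater fish of South America), 3 females and 3 males, were profiled by sequencing poly(A) RNA. Per the labels, the fish were at least 4 years old, 100 to 120 cm long and sampled in their reproductive season. Sex had been read from the gonad contents, spermatozoa in males and primary oocytes in females. RNA integrity numbers lay between 8 and 8.5. Libraries were read on a SOLiD sequencer as 50 nt reads. Each tissue of each fish had 2 libraries, told apart by a prefix of the sample title whose meaning the labels do not spell out, so that 24 libraries were analysed. They are called run 1 and run 2 here. The labels do not tie a library to a sequencing lane, so no batch other than the run could be examined.

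The deposited table held whole-number read counts per gene model and library, with no normalization. Per the series design text, the authors mapped the reads to the genome of another species, the Asian arowana (Scleropages formosus), and the submitters' processing notes name Bowtie without a version. The counting tool, genome build, annotation, mismatches allowed, use of strand, treatment of reads that map to several places and any filter on gene models are not given in the sources used here. Where the 2 species differ in sequence, reads map less often or to a related copy, so that counts compare samples within a gene model more safely than gene models with each other. Levels, ranks and classes of gene models by abundance given here are those of mapped counts and depend on this mapping as well as on expression. Counts of gene models that share sequence with a near-identical copy, or that overlap one on the opposite strand, are uncertain for the same reason.

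The table does not pair its gene model identifiers with gene names, and no annotation of the identifiers was used here. No symbol, function or genome position is therefore given. Gene lists for gonad, germ cell, brain and other cell types, and a set of key sex-determination genes, had been fixed before the data were examined. None of them could be matched to the identifiers, and their tests were not run. Values of single gene models are not reported here.

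Counts of the 2 libraries of a fish and tissue differed by more than sampling noise, with a chi-square per degree of freedom of 2.65 to 9.49 (median 4.15 over 12 pairs). Libraries of different fish of a group differed more, at 9.72 to 42.3 (median 24.9 over 12 pairs). The 2 libraries come from 1 fish and were summed, which gave 12 samples and n = 3 fish in each of 4 groups. Summed totals ran from 5689872 to 13142667 counts, and the median count of a gene model in a sample from 135 to 336. At the median count the spread between fish, a common biological coefficient of variation of 0.154 to 0.203 depending on the comparison, weighed more than counting error. Fitted per gene model over the 12 samples, it had a median of 0.0914 in the fifth with the lowest levels and 0.120 in the highest. In gene models with low counts, counting error can weigh as much or more.

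Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, on summed counts with TMM scaling and the default expression filter (minimum count 10, minimum total count 15). Each sex comparison used the 6 samples of one tissue, each tissue comparison the 6 samples of one sex, and the interaction all 12 samples in 4 groups. A gene model counted as changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are male minus female or gonad minus brain. CPM are counts scaled by the library total and its TMM factor. Log2 CPM for principal components and correlations used a prior count of 2, and median differences by abundance used log2(CPM + 0.5). Single measures of 3 against 3 fish were compared by a two-sided exact permutation test, which cannot give a p below 0.1.

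Brain and gonad with the same number come from the same fish, per the labels. The tissue comparisons within a sex were fitted without this pairing, with the fish as a block in an alternative in edgeR, and the fit over all 6 fish was paired. Deviations from the group means of the 2 tissues of a fish correlated across gene models at r = -0.02, 0.30 and 0.04 in females and -0.05, 0.06 and -0.14 in males. Females and males share only a number.

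The tests, the alternatives and their thresholds were fixed before the data were examined, except where added later. The fixed alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom 3.58.1, other low-count filters, each run alone, each library as a replicate, all 12 samples in one fit, a replicate block, omission of each fish in turn, stricter thresholds and a robust dispersion. Adjusted p-values that DESeq2 left undefined were kept so and not counted as calls, 5165 in the brain. An abundance-trend correction, which removes from each sample its lowess trend (span 0.3) of log2 level on mean abundance, was added after the data were seen, as were other forms of DESeq2, its refits without each fish and the counts at an unadjusted p under 0.05 under each alternative.

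The procedures were tested on simulated counts for 22016 gene models with the means and totals of the real samples, of which 200 were changed, 100 by 2-fold and 100 by 4-fold. In the simulated brain comparison edgeR recovered 86 of the 2-fold and 100 of the 4-fold changes with 22 false calls, and DESeq2 recovered 92 and 100 with 91 false calls. In the simulated gonad comparison edgeR recovered 57 and 97 with 14 false calls, and DESeq2 87 and 99 with 122 false calls. In the simulated tissue comparisons edgeR recovered 64 and 98 in females and 80 and 96 in males, with 14 and 16 false calls, and DESeq2 made 114 and 95 false calls. The 200 changed gene models ease the adjusted p threshold, so the recovery and the number of false calls would differ in data with fewer changes.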

Results

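Poly(A) RNA of gonad and brain was counted in 3 female and 3 male A. gigas to ask which genes are expressed differently between the sexes in each tissue. Totals over the gene models ran from 2753506 to 6718148 counts per library. After the 2 libraries of each fish and tissue were summed, the brain samples of females 1, 2 and 3 held 13142667, 10716132 and 5689872 counts and those of males 1, 2 and 3 held 10587561, 10250653 and 10430277. The gonad samples held 6601933, 9532066 and 11646782 counts in females and 8486409, 11781020 and 8893154 in males. Of 22016 gene models, 22006 were counted in all 24 libraries and 0 were absent from all of them. The mean level of a gene model had a median of 25.0 CPM, and the 5th and 95th percentiles, 5.07 and 125 CPM, lay 24.6-fold apart.

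In the gonad, the edgeR test called 0 of 22001 gene models between testis and ovary (smallest adjusted p = 0.809), with 1283 at an unadjusted p under 0.05, 513 of them higher and 770 lower in males, where chance gives about 1100. DESeq2 called 32 gene models, 4 higher and 28 lower in males, and limma-voom called 0. The DESeq2 count was 17 with the abundance-trend correction and 95 with a replicate block. In the simulated gonad comparison DESeq2 made 122 false calls. Changes simulated there eased the adjusted p threshold, so the 122 do not tell how many of the 32 calls are false. The sexes did not overlap in 11.4% of gene models, against 10% by chance, with 1514 higher and 1000 lower in males. The direction of the unadjusted differences changed with the scaling: 1077 were higher and 363 lower in males with upper-quartile scaling, and 2212 and 205 with total counts alone, which moved the median log2 fold change of all gene models to 0.21. Without female 1 edgeR called 2 gene models, both lower in males. With all 12 samples in one fit 2087 were at an unadjusted p under 0.05, 1231 higher and 856 lower in males. The count at an unadjusted p under 0.05 was 847 without female 2, 814 without male 1, 536 without male 2 and 2092 without male 3.

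In the brain, edgeR called 0 of 22015 gene models between males and females (smallest adjusted p = 0.130), with 4012 at an unadjusted p under 0.05, 1572 higher and 2440 lower in males, where chance gives about 1100. The sexes did not overlap in 26.5% of gene models, against 10% by chance, with 2982 higher and 2860 lower in males. DESeq2 called 1358 gene models, 96 higher and 1262 lower in males, with a median absolute log2 fold change of 0.50 and 142 of at least 2-fold. DESeq2 called 713 with a replicate block and made 91 false calls in the simulated brain comparison. Changes simulated there eased the adjusted p threshold, so the 91 do not tell how many of the 1358 calls are false. Of the 1358, 60.0% belonged to the fifth of gene models with the highest levels. limma-voom called 4, all lower in males. Without female 1 the edgeR count was 575, 20 higher and 555 lower in males. The DESeq2 count was 383 without female 2, 605 without male 2 and 792 without male 3, and the count at an unadjusted p under 0.05 in edgeR was 2464 without male 2. With all 12 samples in one fit 2160 were at an unadjusted p under 0.05, 1114 higher and 1046 lower in males. With upper-quartile scaling 3513 of the unadjusted differences were higher and 1456 lower in males, and with total counts alone 8828 and 480, with a median log2 fold change of all gene models of 0.31.

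How counts were spread over gene models was compared between the sexes, with 3 against 3 fish, too few for a p under 0.05. The 220 most abundant gene models held 22.3 ± 4.74% of counts in female brain and 12.8 ± 1.55% in male brain (SD, n = 3, exact permutation p = 0.1, the smallest possible). In the gonad they held 23.4 ± 2.66% in females and 18.2 ± 4.42% in males (SD, n = 3, exact permutation p = 0.1, the smallest possible). In the tenth of gene models with the lowest levels the median male minus female difference on the log2(CPM + 0.5) scale was 0.15 in brain and 0.11 in gonad. In the tenth with the highest levels it was -0.20 in brain and -0.16 in gonad. These signs hold under TMM scaling. With total counts alone the median log2 fold change of all gene models was 0.31 in brain and 0.21 in gonad.

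**Figure D1:**
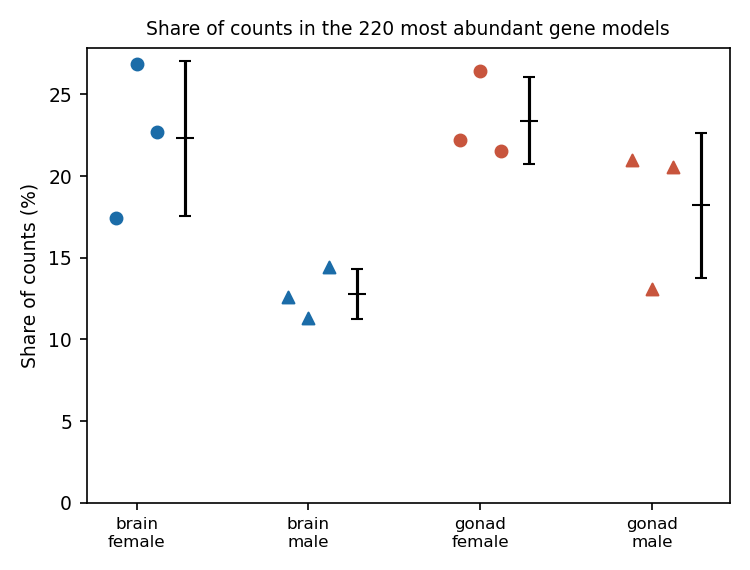
Share of counts, in percent (vertical axis, from 0), held by the 220 gene models with the highest mean level, in the 4 groups (horizontal axis). Points are fish, circles females and triangles males, and the bar is the mean ± SD (n = 3); the 3 male brains lie between 11.3% and 14.4%, below all 3 female brains.

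**Figure D2:**
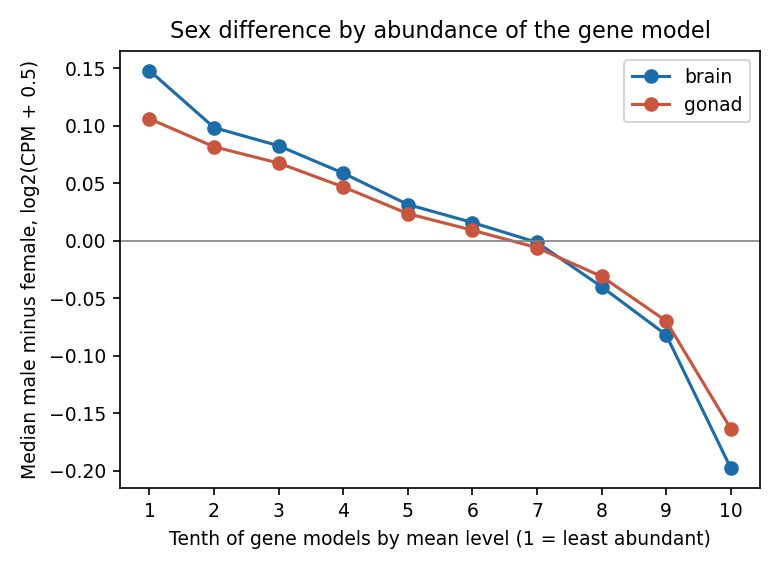
Median male minus female difference on the log2(CPM + 0.5) scale (vertical axis) in 10 classes of gene models by mean level, from the least to the most abundant (horizontal axis). Each point is the median over about 2202 gene models, in brain and in gonad, and both lines go from above 0 (0.15 and 0.11) to below 0 (-0.20 and -0.16). The place of 0 depends on the TMM scaling.

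Whether the sex difference itself differed between gonad and brain was tested as an interaction. The edgeR test called 0 of 22015 gene models (smallest adjusted p = 0.9998), with 571 at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Without female 1 edgeR called 7, 2 with a positive and 5 with a negative interaction.

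Gonad and brain were compared within each sex, without pairing the tissues of a fish. In females edgeR called 0 gene models between gonad and brain, with 709 at an unadjusted p under 0.05, where DESeq2 called 11, 6 of them higher in the gonad, and limma-voom 0. In males edgeR called 0, with 973 at an unadjusted p under 0.05, where DESeq2 called 36, 33 of them higher in the gonad, and limma-voom 0. DESeq2 made 114 false calls in the simulated tissue comparison of females and 95 in that of males. The changes put into the simulated counts eased the adjusted p threshold. These numbers therefore do not tell how many of the DESeq2 calls between the real tissues are false. Without male 3 edgeR called 1 in males, higher in the gonad. With total counts alone the median log2 fold change of all gene models in males was -0.16. Over all 6 fish, paired, edgeR called 0 (smallest adjusted p = 0.0533), with 1263 at an unadjusted p under 0.05.

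The profiles of the 2 tissues lay close together. Across gene models, which are not independent replicates, log2 CPM of the gonad and brain of 1 fish correlated with a median r of 0.969 (6 pairs), and samples of the same tissue and sex from different fish with a median r of 0.963 (12 pairs). Tissue accounted for 9.64% of the variance of log2 CPM, against a median of 7.60% and a highest value of 9.88% over the other assignments of the tissue labels within fish, and 3 of the 32 assignments gave as much (exact permutation p = 0.0938, the smallest possible being 0.0312). Sex accounted for 18.3%, against a median of 9.01% and a highest value of 17.1% over the other splits of the fish (exact permutation p = 0.1, the smallest possible). No gene model was at least 1.5-fold above the other 9 samples in all 3 samples of female brain, male brain, ovary or testis. The largest ratio of a mean gonad level of either sex to the mean brain level, taken over both sexes, was 12.6. Within a sex and in either direction, the largest absolute log2 fold change fitted between the tissues was 5.56 in females and 4.10 in males.

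**Figure D3:**
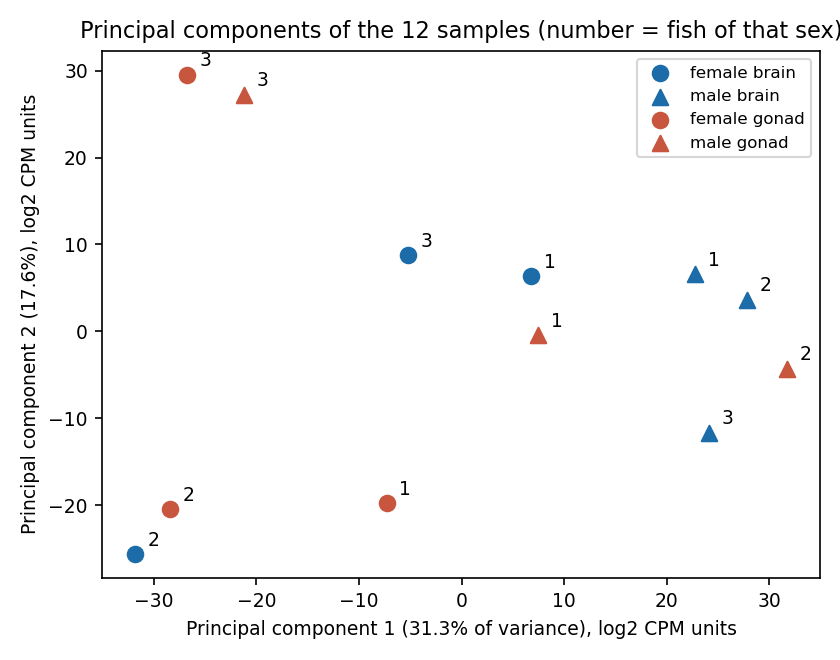
First (horizontal, 31.3% of variance) and second (vertical, 17.6%) principal components of log2 CPM for the 12 samples, with blue for brain, red for gonad, circles for females, triangles for males and numbers for the fish of that sex. Brain and gonad samples are interspersed, and the 3 male brains lie together at first-component values from 22.8 to 27.8.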

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

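The trend correction, the other forms of DESeq2, its refits without single fish and all alternatives for counts at an unadjusted p under 0.05 were chosen after the data were seen. In edgeR, other scalings, filters, single runs, all 12 samples in one fit, stricter thresholds, a robust dispersion and the trend correction each left 0 calls wherever they were run. So did the replicate block, 0 calls in all 5 comparisons, the fish being the block across tissues. Females and males share only a number, with same-number deviations at r = 0.04, -0.14 and -0.14 in brain and 0.10, 0.04 and 0.26 in gonad. Leaving out 1 fish gave 0 to 2 calls between the sexes in gonad, 0 to 575 in brain, 0 to 1 between tissues in males, 0 in females and 0 to 7 for the interaction, the highest without female 1, or male 3 for male tissues. DESeq2 called 32 in gonad, 1358 in brain, 11 and 36 between tissues in females and males and 2 for the interaction. With TMM scaling it called 34 in gonad and 1326 in brain, with the trend correction 17 and 922, and with the replicate block 95 and 713. Without 1 fish it called 383 to 1160 in brain, with 383 without female 2, 605 without male 2 and 792 without male 3. limma-voom called 4 in brain and 0 elsewhere. Treating each library as a replicate, which treats 2 libraries of a fish as independent, called 1 in gonad and 2603 in brain. Why the counts moved when 1 fish was left out was not tested. The share of calls higher in males has no value without calls, the gene lists were not run, and the filter on gene models 50 times higher in gonad removed 0. In simulated counts with these depths and 3 fish per sex, edgeR recovered 57% of 2-fold changes in gonad and 86% in brain. These shares hold for the simulated set of changes, which eased the adjusted p threshold. Recovery in data with fewer changes can be lower. As many changes as were simulated would have given calls if the real spread were as simulated, which was not tested. A smaller number of 2-fold changes can be missed, so the 0 edgeR calls do not show that there are none.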

Other observations

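The split counts for the edgeR sex comparisons, the trend-corrected refits without single fish, the comparison of folds before and after correction and all trend corrections were chosen after the results were seen. Some gene models stood far above all other samples in 1 sample. In the 6 female samples 317 gene models were at least 2-fold above each of the other 11 samples on the CPM + 0.5 scale, and in the 6 male samples 64. The samples overlapped in brain, with 15, 87 and 23 in females 1, 2 and 3 and 3, 9 and 18 in males 1, 2 and 3, and not in gonad, with 79, 56 and 57 in females and 7, 14 and 13 in males. Of these 381, 380 were highest in both runs of that sample. The difference between the sexes in this count was not tested.

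Whether the more even spread of counts in male brains was the whole source of the DESeq2 count in brain was not settled. Over the 1358 gene models called, the median log2 fold change in the direction of the call was 0.50 (quartiles 0.40 and 0.69, median SE 0.13) before the abundance-trend correction and 0.43 (quartiles 0.33 and 0.60, median SE 0.13) after it. Without each fish the median kept 0.829 to 0.883 of its uncorrected value. Kept folds do not settle the question, since a gene model can lose its call with most of its fold kept. After the correction DESeq2 called 922 gene models, 822 of them among the 1358 called before, 85.8% of them lower in males. Without single fish the corrected count was 777 (female 1), 129 (female 2), 178 (female 3), 207 (male 1), 269 (male 2) and 137 (male 3), from 0.163 to 0.670 of the uncorrected counts. The first criterion for the trend was a corrected count below 0.50 of the uncorrected one. The full data, at 0.679, did not meet it, and the refits without each fish but female 1 did. With the correction the folds of the 1358 shrank without each fish. Their median SE rose without female 3 (0.15 to 0.17), male 1 (0.16 to 0.19) and male 3 (0.16 to 0.18) and not without the others. The trend may therefore have supplied part of the calls. Undefined adjusted p-values among the 1358 also rose, from 92 to 301 without female 3 and from 99 to 444 without male 1. They fell from 404 to 366 without female 2, 237 to 170 without male 2 and 234 to 196 without male 3. After the correction 1256 of the 1358 stayed at an unadjusted DESeq2 p under 0.05 with all fish, and 882 to 1126 without each fish in turn. Whether a single fish was the source of these folds was not settled for the 1358 gene models. Without each fish in turn their median log2 fold change before the correction was 0.43 to 0.57. The lowest, without female 2, had a median SE of 0.17, with 1174 of the 1358 at an unadjusted DESeq2 p under 0.05. The 1358 were picked with all fish included, which can raise such folds, so folds kept without 1 fish do not decide this. The count itself leaned on single fish. It was 383 without female 2, where 404 of the 1358 had an undefined adjusted p, and 1160 without female 1. Of the 10 splits of the brain samples into 3 and 3, only the real 1 gave as many calls, with 81 as the highest other, but 10 splits are too few for a share under 0.05, and a difference between the sexes was not separated from these.

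Brain and gonad profiles hardly differed, which is unusual for such unlike tissues. Tissue labels swapped within some fish were argued against for differences as large as those simulated, 4-fold in 200 gene models, since the highest count among the other assignments of the 32 was 0 calls, where the right assignment of a simulated swap of 1 fish gave 208. Smaller differences stay open, since 5 assignments gave more gene models at an unadjusted p under 0.05 (1847, 1779, 1674, 1617 and 1264) than the 1263 as labelled, and swaps between fish were not tested. A component of reads common to all libraries, such as reads placed in the arowana genome without regard to tissue, would flatten differences most in gene models with low counts, between testis and ovary as well as between tissues. The spread between fish went that way. The biological coefficient of variation was 1.31 times as high in the fifth of gene models with the highest levels as in the fifth with the lowest, and 1.27 to 1.39 times without each fish. This ratio does not decide, since fish of a group also differed in the share of counts in the most abundant gene models. In female brain the top 220 held 17.4% to 26.9%, and the abundance trend was not removed before the ratio was taken. Such a component would also leave counts in all libraries, and 22006 of 22016 gene models were counted in all 24. That number does not decide either, since the sources do not say whether gene models were filtered. Reads were not analysed here, so such a component remains a hypothesis. The 0 edgeR calls between testis and ovary do not show that they are alike, and a real similarity of the tissues was not tested.

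The sex differences of brain and gonad went together across gene models (Pearson r = 0.53, Spearman rho = 0.53, over gene models, which are not independent). The trend of level with abundance was argued against as the whole cause in the full data. There r was 0.42 after its removal, against 0.209 in the highest other split of the fish after removal. Without each fish r kept 0.583 to 0.847 of its value. The relation leaned on male 2, without which r was 0.21, or 0.12 after the correction. That 0.12 is no larger than other splits of the fish gave, so without male 2 the trend is not decided on. Among 10 splits of the 6 fish only the real 1 gave as large an r, with 0.28 as the highest other, which is too few splits for a share under 0.05. A shared effect of sex on both tissues may remain, but RNA handling per fish was not tested.

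For the counts at an unadjusted p under 0.05 the 10 splits were too few for a share under 0.05. In brain, 4012 gene models at an unadjusted p under 0.05 compared with 1375 in the highest other split, and 1 of 10 splits gave as many. In gonad, 1283 compared with 3817 in the highest other split, female 1, male 1 and male 2 against the rest, and 3 of 10 splits gave as many. What sets that split apart was not tested. For changed gene models the splits decide nothing, since the real count was 0 in gonad, brain, both tissue comparisons and the interaction and 10 of 10 splits necessarily gave as many. The highest other split gave 3 in female tissues and 0 elsewhere.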
